A study of Mus musculus with 31 samples.

How the data were processed

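RNA was measured in 31 libraries of sorted mouse natural killer (NK) cells, which are innate lymphocytes that kill tumour and infected cells. The series crosses 3 genotypes with 3 conditions. The genotypes were wild type (WT), knockout of the type II receptor of transforming growth factor beta (TGFBRII KO; gene Tgfbr2) and knockout of CIS (CIS KO; gene Cish), a suppressor of cytokine signalling that restrains the response to interleukin 15. The conditions were unstimulated cells, 4 h with the cytokine TGFB1 and 24 h with TGFB1. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a directional (strand-keeping) Illumina kit.

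The data are a table of raw counts per gene that the authors deposited, with 1 column per library and Entrez gene identifiers. The deposited counts were made with FastQC, Trimmomatic, Subread, featureCounts, Picard and SAMtools on the mouse build mm10, per the submitters' processing notes, which give no versions and no roles. The strand setting, the counting options and whether duplicate reads were removed are not given in the sources used here. Reads from overlapping or near-identical genes may therefore be split between them or left out in a way that cannot be traced. Values of multigene families (Klra receptors, granzymes, immunoglobulin constant regions) are uncertain in that sense. Gapdh, of the glycolysis genes, had only 0 to 8 counts per library and Tmsb4x 0 to 1, and the reason was not tested.

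The table held 27179 genes, of which 9782 had 0 counts in all libraries. Symbols and coordinates came from the RefSeq annotation of GRCm38.p6 (the mm10 assembly) for 25275 identifiers, and from GENCODE M21 for 18 more. The 1886 identifiers without a symbol held 0.96% of the counts. Column names were matched to the sample titles, and each column belonged to 1 sample.

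Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed by filterByExpr on the 9 groups, which left 10275 genes. Library sizes were scaled by TMM. All 31 libraries were fitted together in 9 groups with 1 shared estimate of the spread, because WT at 4 h had 2 libraries. Each comparison used edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at an adjusted p under 0.05. Response differences between genotypes were tested as interaction terms. Values are given as log2 fold change ± standard error, taken from the fold change and its F statistic, and as CPM (library-scaled counts, with TMM) as mean ± SD over the libraries of a group. All adjusted p-values of genes come from this test. Where a group had 0 counts of a gene in all its libraries, the fold is a lower bound against a floor of 3 counts over that group. Such bounds cover counting error only.

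Before the data were examined, 24 gene lists, the design, the alternatives and the rule for named genes were fixed. The lists covered TGF-β feedback genes, tissue residency and type 1 innate lymphoid genes, circulating mature NK genes, cytotoxic machinery, cytokines and chemokines, interleukin 15 and STAT5 response, NK receptors, glycolysis, oxidative phosphorylation, cholesterol synthesis, amino acid and mTORC1 response, ribosome biogenesis, cell cycle, type I interferon response, immediate early genes, p53 and apoptosis, hypoxia and mitochondrially encoded RNA. They also covered markers of T cells, B cells, myeloid cells, type 2 and 3 innate lymphoid cells, erythroid cells and platelets, and stroma or epithelium. Lists with at least 2 measured genes (22 of 24) were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation. Named genes were Tgfbr2 and Cish, the 10 called genes with the largest change in each direction whose libraries did not overlap and whose mean was at least 5 CPM in the higher group (response differences without the overlap condition), and up to 4 members of each described list with the smallest p. Unnamed gene models were left out. Smad7 and Skil fell outside this rule and were chosen after their values were seen, as were other genes named as such.

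Total counts per library ran from 297561 to 1403005, with a median of 736193, which is shallow for genes with few transcripts. In data simulated from these libraries with 10275 genes, the test recovered 47.8% of 1.5-fold, 70.1% of 2-fold and 97.0% of 4-fold changes for WT at 24 h, with 4.0% of its calls false. The shares were 22.4%, 67.2% and 87.9% for WT at 4 h (5.6% false), and 35.8%, 73.1% and 95.5% for TGFBRII KO at 24 h (6.8% false). They were 25.4%, 55.2% and 87.9% for the difference between the CIS KO and WT responses at 24 h (7.4% false), and 11.9%, 37.3% and 80.3% at 4 h (4.4% false). The simulated counts rose in proportion to library size and held no structure between samples, unlike the real counts described below. These shares therefore may not hold for the real data.

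In the deposited counts, abundant genes levelled off with depth. Gzma had 439 to 589 counts in every library. Over genes with 0.3 to 1 counts per base of exon, a gene's log count rose with the log library total with a slope of 0.31, against 1.18 for genes with 0.01 to 0.02 counts per base. Below 0.005 counts per base the median slope was 1.43. Fold changes of abundant genes therefore depend on depth, and those of sparse genes can do so in the other direction. The role of Picard, which can remove duplicate reads, is not given in the sources used here. The labels call the libraries biological replicates and name no animals, so p-values measure the spread between these samples. Every TGFBRII KO library held both Xist (12.6 to 131 CPM) and transcripts of Y chromosome genes (187 to 451 CPM). Its cells may therefore come from several animals, and whether p-values measure the spread between animals is not known. Within groups, 40 pairs of libraries were compared by chi-square, and 9 had a value per degree of freedom under 1. All pairs of TGFBRII KO at 24 h were among these (0.772 to 0.999), no more spread than counting alone gives. Such values included TGFBRII KO unstimulated replicates 1 and 2 (0.872), whose Xist levels were 72.2 and 22.9 CPM, so they did not single out a library deposited again, and none were merged.

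The 8 alternatives set along with the lists were DESeq2 1.42.0, RLE factors, library size alone, no low-count filter, only the compared groups, the replicate number as a block, an estimated inter-gene correlation, and leaving out each library in turn. Chosen after seeing the data were 4 more: the log library total as a covariate, counts corrected for levelling off, only genes below 0.05 counts per base, and the male share of each library as a covariate. The male share is the summed CPM of Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d over the mean of that sum in CIS KO libraries. It ran from 0.00297 to 1.199, so it is an index of Y-linked RNA and not a measured share of male cells.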

Results

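The series asked how TGFB1 changes the transcripts of NK cells, and how that response depends on the TGF-β receptor and on CIS. Unstimulated cells were measured in 4 WT, 3 TGFBRII KO and 4 CIS KO libraries. At 4 h of TGFB1 there were 2 WT, 3 TGFBRII KO and 4 CIS KO libraries, and at 24 h there were 4, 3 and 4. Total counts ran from 297561 to 1135104 in WT, from 701095 to 862331 in TGFBRII KO and from 392266 to 1403005 in CIS KO. No group of cells kept for 24 h without TGFB1 was analysed here, so a response is the change against unstimulated cells, with any effect of time in culture included. The genotypes also differed in sex-linked transcripts. Xist, made from the inactive X chromosome, ran from 91.1 to 222 CPM in WT, from 12.6 to 131 CPM in TGFBRII KO and from 0 to 5.22 CPM in CIS KO libraries, and the summed CPM of Ddx3y, Eif2s3y, Uty and Kdm5d, on the Y chromosome, ran from 1.38 to 124, from 187 to 451 and from 392 to 558.

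Cish transcripts (Entrez 12700; mm10 chromosome 9, 107296659 to 107302784) were lower in CIS KO at every time. In unstimulated cells Cish stood at 25.2 ± 6.76 CPM in CIS KO (n = 4) and 157.6 ± 21.6 CPM in WT (n = 4), a log2 difference of -2.66 ± 0.17 (adjusted p = 7.1e-13). The difference was -2.44 ± 0.18 at 4 h and -2.07 ± 0.13 at 24 h. Tgfbr2 (Entrez 21813; mm10 chromosome 9, 116087695 to 116175363) was at 229.7 ± 8.18 CPM in unstimulated TGFBRII KO (n = 3) and 212.8 ± 26.6 CPM in WT, a log2 difference of 0.12 ± 0.13 (adjusted p = 0.87). Counts per whole gene keep reads from exons outside a deleted part, so the Tgfbr2 level checks neither the label nor the deletion. Smad7, an inhibitor of TGF-β receptor signalling that the pathway itself induces (mm10 chromosome 18, 75367365 to 75395935), went from 45.01 ± 5.94 CPM in unstimulated WT cells to 134.7 ± 9.74 at 4 h (n = 2) and 116.8 ± 17.3 at 24 h, and from 35.5 ± 1.68 to 117.7 ± 13.3 and 96.8 ± 27.8 CPM in CIS KO. In TGFBRII KO, Smad7 was at 35.6 ± 3.38, 33.6 ± 3.86 and 33.6 ± 5.45 CPM, with log2 changes of -0.09 ± 0.23 at both times.

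**Figure D1:**
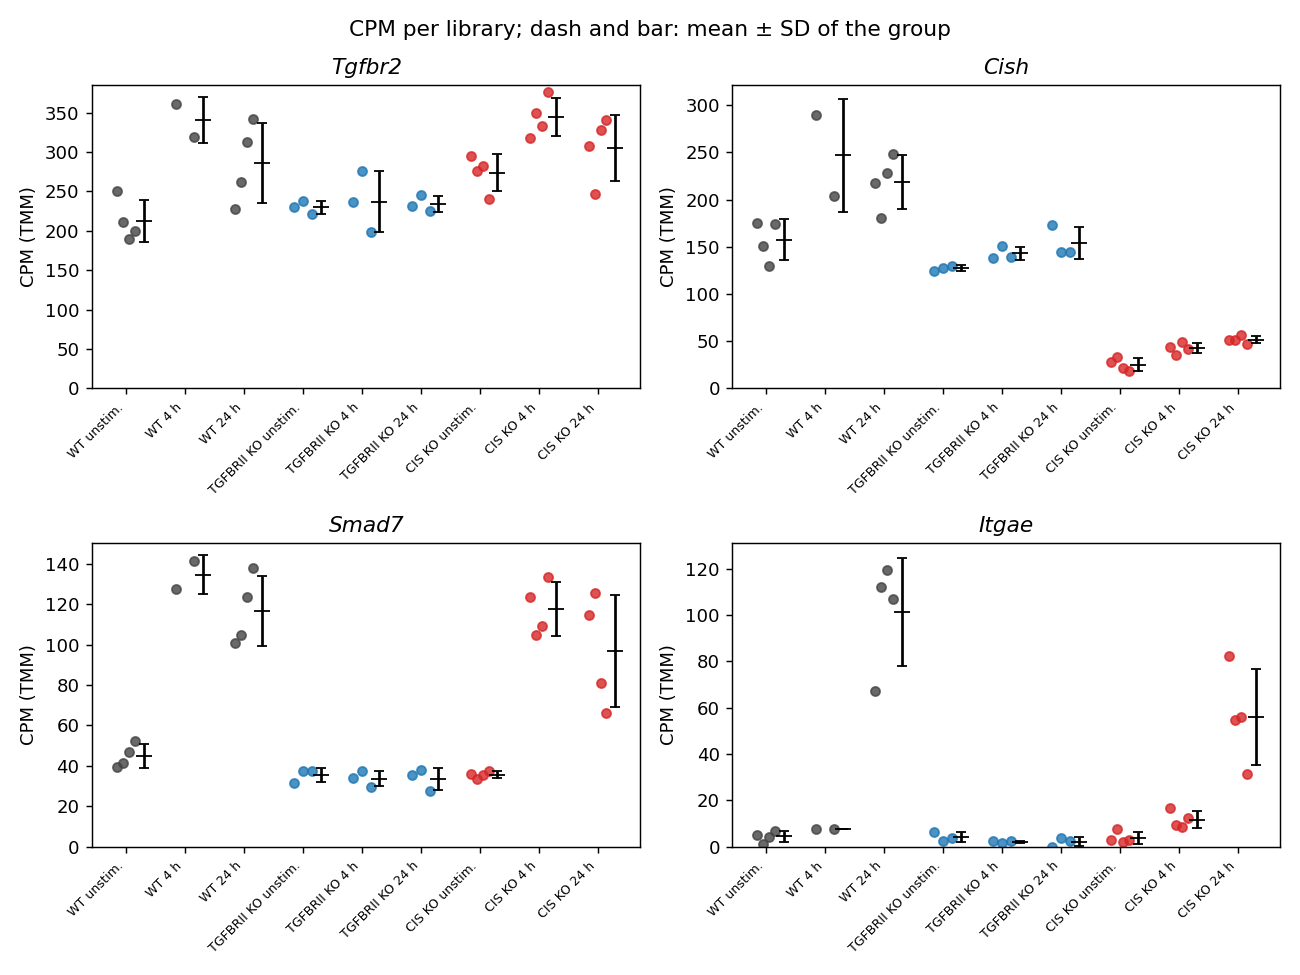
CPM (TMM-scaled) of Tgfbr2, Cish, Smad7 and Itgae in each of the 31 libraries by group, with the dash and bar giving the group's mean ± SD. Smad7 was at 134.7 CPM in WT at 4 h and 33.6 CPM in TGFBRII KO at 4 h, and Itgae was at 101.4 CPM in WT at 24 h and 2.05 CPM in TGFBRII KO at 24 h.

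At 4 h, TGFB1 raised the transcripts of its own feedback loop in WT cells. Pmepa1, which holds back SMAD activation, went from 22.8 ± 5.82 to 623 ± 59.3 CPM (log2 4.76 ± 0.25), Ski, a SMAD co-repressor, rose by 2.00 ± 0.12, Tgfb3 by 2.83 ± 0.21 and Ldlrad4 by 3.24 ± 0.31. Of the 14 measured feedback genes, 9 rose and 1 fell (9 and 2 adjusted over the list alone). Among 14 residency genes, 7 rose and 1 fell (7 and 2 adjusted over the list alone), led by Nt5e, the ectoenzyme CD73 that makes adenosine (3.69 ± 0.26), and Rgs1 (1.56 ± 0.22). Transcripts of Igha, whose germline form TGF-β induces in B cells, went from 1.00 ± 1.31 to 81.4 ± 17.7 CPM, and those of Pacsin1, a membrane-remodelling protein, from 0.834 ± 1.18 to 70.2 ± 14.2 CPM. Cholesterol synthesis genes fell, with 13 of 17 lower and 0 higher over all genes and over the list alone, among them Sqle (-1.42 ± 0.15) and Cyp51 (-1.12 ± 0.15). They fell in TGFBRII KO at 4 h too, 12 of 17, and 0 of 17 differed between the responses. This fall is therefore not shown to need the receptor. The activating receptor gene Ncr1 fell by 1.04 ± 0.14 and the kinase gene Pim2 by 1.39 ± 0.16. Nudt10 was at 0 in both 4 h libraries, at least 3.38-fold lower than in unstimulated cells.

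Over all genes, 709 were higher and 517 lower in WT at 4 h. With library size alone as the scaling, the share of calls that were higher was 41.2% in place of 57.8%, and with DESeq2 it was 69.4%, so the balance of rises and falls is not settled. The feedback, residency and cholesterol lists held with an estimated correlation (adjusted p = 5.53e-07, 0.0015 and 0.0132). The fall of the ribosome biogenesis list (1 of 16 rose and 5 fell; 2 and 10 adjusted over the list alone) had an adjusted p = 0.152 with an estimated correlation, as had the p53 list (2 of 12 rose and 1 fell; 3 and 1 adjusted over the list alone). The rises of the immediate early list (3 of 13; 7 rose and 1 fell adjusted over the list alone) and of mitochondrially encoded RNA (3 of 10; 6 adjusted over the list alone) had an adjusted p = 0.23 with an estimated correlation, as had the fall of 3 of 21 cell cycle genes. Oxidative phosphorylation, with 0 of 24 higher and 1 lower (5 and 1 adjusted over the list alone), was at 0.681. Without WT 4 h replicate 1, the shallowest library at 297561 counts, 583 genes were called, without WT 4 h replicate 4 there were 730 higher and 322 lower, with 607 of the 1226 calls shared, and 722 were called with only these 6 libraries in the fit and 662 with a replicate block. The rises of the abundant granzyme genes Gzma (0.93 ± 0.27) and Gzmc (0.85 ± 0.27) involve counts that level off with depth, and with depth as a covariate the Gzmc value was -0.004. Abundant genes tilted as a class: among 864 genes with at least 0.05 counts per base, 122 were higher and 19 lower. Their median log2 change was 0.239, against -0.128 for 4586 genes below 0.01 counts per base.

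By 24 h, proliferation genes had fallen in WT cells. All 21 measured cell cycle genes fell, also when adjusted over the list alone, with a median log2 change of -1.54. Ccna2, a cyclin of S phase and mitosis, dropped from 224 ± 25.0 to 42.5 ± 12.3 CPM (log2 -2.37 ± 0.15), and Mcm3, part of the replicative helicase, fell by 1.51 ± 0.12. Itgae, which encodes the integrin CD103 of tissue-resident lymphocytes (mm10 chromosome 11, 73090505 to 73147449), rose from 4.36 ± 2.36 to 101.4 ± 23.4 CPM (log2 4.51 ± 0.32). It was 1 of 8 residency genes of 14 that rose (9 rose and 2 fell adjusted over the list alone), with Nt5e at 2.68 ± 0.24 and Itga1, the integrin CD49a, at 0.81 ± 0.12. Feedback genes were raised as a list (9 of 14 rose and 1 fell, also when adjusted over the list alone), with Pmepa1 at 4.36 ± 0.22 and Tgfb3 at 3.14 ± 0.16. Igha reached 158 ± 28.1 CPM and Pacsin1 156 ± 21.3 CPM.

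The cholesterol and amino acid lists fell as well in WT cells at 24 h, and single effector genes did. Cholesterol synthesis had 15 of 17 genes lower (also when adjusted over the list alone), such as Nsdhl (-1.01 ± 0.15). The amino acid and mTORC1 list had 6 of 14 lower (8 adjusted over the list alone), with Mthfd2, a mitochondrial folate enzyme, at -1.36 ± 0.11 and Phgdh, the first enzyme of serine synthesis, at -1.28. The pore-forming protein gene Prf1 went from 172 ± 7.37 to 83.7 ± 20.3 CPM (log2 -1.05 ± 0.17), with 3 of 16 cytotoxic genes lower and 1 higher over all genes and over the list alone. Havcr2, the inhibitory receptor TIM-3, fell by 1.59 ± 0.15, with 3 of 19 NK receptor genes lower and 1 higher. The chemokine gene Ccl9 fell from 89.0 ± 19.6 to 7.42 ± 2.15 CPM. The circulating NK list had 4 of 11 genes lower (4 adjusted over the list alone), including Klrg1 (-0.50) and Ly6c2 (-0.63). In the interleukin 15 and STAT5 list, 3 of 15 genes rose and 4 fell (3 and 5 adjusted over the list alone), with Il2ra at -0.93 ± 0.19. In total, 989 genes were higher and 1177 lower. The feedback, residency, cell cycle, amino acid and cholesterol lists held with an estimated correlation (adjusted p = 3.47e-08, 0.0071, 9.48e-06, 0.0109 and 0.0423). The cytotoxic, NK receptor, circulating and interleukin 15 lists passed camera with neither correlation. Counts of the cytotoxic genes Gzma, Gzmb and Gzmc level off with depth (slopes 0.16, 0.37 and 0.12). A change in these genes may therefore show smaller than it was.

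In TGFBRII KO cells, ribosome biogenesis genes rose after 4 h, 13 of 16 over all genes and over the list alone, with Nolc1, a nucleolar chaperone, at a log2 change of 1.26 ± 0.14 and Mybbp1a rising by 0.92 ± 0.11. Cholesterol genes fell, 12 of 17 (13 adjusted over the list alone), such as Fdft1 (-0.92 ± 0.14) and Sqle (-0.82 ± 0.11). Low-oxygen response genes Ankrd37 (2.24 ± 0.29), Vegfa (1.89 ± 0.29) and Hk2, a glycolytic enzyme (1.20 ± 0.24), rose, and 3 of 12 hypoxia genes did (4 adjusted over the list alone; adjusted p = 0.561 with an estimated correlation). Among p53 targets, 4 of 12 rose (also over the list alone), with Cdkn1a at 0.59 ± 0.12 and Aen at 1.28 ± 0.27. No feedback gene of 14 was called. T cell marker genes Bcl11b (-0.80 ± 0.18), Cd3d (-0.60 ± 0.19) and Cd3g (-0.51 ± 0.15) fell beside these groups, 3 of 6 measured, also over the list alone. Cell cycle genes fell too, 3 of 21 (7 adjusted over the list alone; adjusted p = 0.389 with an estimated correlation).

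The test called 470 genes higher and 354 lower in TGFBRII KO at 4 h. The ribosome biogenesis, cholesterol, T cell and p53 lists held with an estimated correlation (adjusted p = 1.27e-06, 0.00185, 0.0156 and 0.0497). DESeq2 called 434 genes, the depth covariate 1360, the fit on these 6 libraries alone 1336, and the fits without unstimulated replicate 1, unstimulated replicate 2 or 4 h replicate 3 called 403, 459 and 447. Of the calls in WT and TGFBRII KO at 4 h, which share no library, 37 were higher in both where independent lists would share 32.4, and 87 were lower in both where they would share 17.8. In opposite directions, 24 were higher in WT and lower in TGFBRII KO, and 38 were lower in WT and higher in TGFBRII KO.

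After 24 h, 2 genes were called in TGFBRII KO. Chac1, a glutathione-degrading enzyme of the amino acid stress response, rose from 23.7 ± 5.25 to 55.7 ± 8.60 CPM (log2 1.23 ± 0.23, adjusted p = 0.0318), and Kdm4b, a histone demethylase, from 35.2 ± 4.99 to 70.3 ± 8.60 CPM (0.99 ± 0.19). No hypoxia gene was called over all genes, and 7 of 12 were higher adjusted over the list alone (median log2 change 0.49, adjusted p = 0.0686 with an estimated correlation). Cholesterol genes numbered 0 called and 4 higher adjusted over the list alone, and the amino acid list had 1 rise, Chac1, in either adjustment (adjusted p = 0.0686 with an estimated correlation for each). The camera calls of residency, glycolysis, NK receptors and mitochondrially encoded RNA, each with 0 genes called, were lost too, with adjusted p = 0.128, 0.315, 0.344 and 0.344 with an estimated correlation. At an unadjusted p under 0.05 there were 730 genes. DESeq2 called 0, as did the replicate block, and leaving out any of unstimulated replicates 1 to 3 or of 24 h replicates 2 and 3 gave 0. The fit on these 6 libraries called 206 (73 higher, 133 lower) and the fit without a low-count filter 79 (25 higher, 54 lower). In both, falls outnumbered rises. The depth covariate gave 13.

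In CIS KO cells at 4 h, the feedback and residency genes rose as lists. Ski rose by 2.47 ± 0.12, Pmepa1 by 4.85 ± 0.25 and Nt5e by 4.32 ± 0.27, with 9 of 14 feedback genes (10 higher and 1 lower adjusted over the list alone) and 6 of 14 residency genes higher (7 adjusted over the list alone). Pacsin1 was at 0 in the 4 unstimulated CIS KO libraries and at least 31.9-fold higher at 4 h, and Ncmap, a myelin-associated protein gene, at least 16.4-fold. Ncr1 fell by 1.32 ± 0.12 and the phosphatase gene Dusp7 by 2.43 ± 0.29. Cell cycle genes fell, 18 of 21 (21 adjusted over the list alone), for example Mcm3 (-0.73 ± 0.12). Cholesterol genes fell, as they did in TGFBRII KO at 4 h, 13 of 17 in either adjustment, for example Sqle (-1.02 ± 0.11). The test called 797 genes higher and 647 lower, and these 4 lists held with an estimated correlation (adjusted p = 3.92e-09, 0.00125, 0.00799 and 0.00262). With library size alone 668 were higher and 766 lower, so their balance depends on the scaling.

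CIS KO cells at 24 h had 1264 genes higher and 1205 lower. Pmepa1 rose by 4.30 ± 0.25, Tgfb3 by 3.46 ± 0.19 and Itgae from 3.73 ± 2.49 to 56.0 ± 20.7 CPM (log2 3.85 ± 0.41), with 9 of 14 feedback genes and 7 of 14 residency genes higher and 1 residency gene lower, in either adjustment. Pacsin1 was at least 92.0-fold higher. Cholesterol genes fell (16 of 17 in either adjustment; Hmgcs1 -1.12 ± 0.13), as did the amino acid list (10 of 14, with 1 higher; 11 and 1 adjusted over the list alone; Mthfd2 -1.07 ± 0.10), cell cycle (19 of 21; 20 adjusted over the list alone; Ccna2 -0.75 ± 0.14), ribosome biogenesis (9 of 16; 12 adjusted over the list alone; Nop56 -0.54 ± 0.14) and circulating NK genes (6 of 11; 7 adjusted over the list alone; Cma1 -1.28). Cytotoxic genes had 5 of 16 lower and 1 higher (8 and 1 adjusted over the list alone; adjusted p = 0.18 with an estimated correlation), with Prf1 at -1.13 ± 0.16. The chemokine gene Ccl3 fell by 1.32 ± 0.17, in a list with 4 of 10 lower and 1 higher (adjusted p = 0.241 with an estimated correlation).

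The feedback, residency, circulating, cholesterol, amino acid, ribosome and cell cycle lists held in CIS KO at 24 h with an estimated correlation (adjusted p = 1.14e-07, 0.00477, 0.0177, 0.00454, 0.00477, 0.0186 and 0.021). The falls of NK receptors (6 of 19), the interleukin 15 list (4 of 15), glycolysis (5 of 14), oxidative phosphorylation (6 of 24) and mitochondrially encoded RNA (5 of 10), with 7, 6, 5, 6 and 6 adjusted over the list alone, did not, with adjusted p = 0.241, 0.203, 0.509, 0.518 and 0.0876 with an estimated correlation. Abundant genes were part of this picture: among 864 genes with at least 0.05 counts per base, 19 were higher and 250 lower, and their counts level off with depth. The fit on these 8 libraries called 1421 genes, and without 24 h replicate 2, the deepest library at 1403005 counts, 765 were higher and 867 lower. Falls outnumbered rises also with DESeq2 (773 higher, 964 lower) and RLE factors (1144 and 1280), while library size alone gave 1487 and 1050, so the balance is not settled.

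Markers of other cell types were few. Ighm, the constant region of immunoglobulin M and the 1 measured B cell gene, rose in WT (2.15 at 4 h, 2.50 ± 0.20 at 24 h) and in CIS KO (2.74 and 3.19). In WT at 24 h the T cell genes went both ways, with Lat at 0.47 ± 0.11, Bcl11b at -0.68 ± 0.18 and Cd3d at -0.58 ± 0.15. Of 3 myeloid genes 0 were called in any response, of 2 genes of type 2 and 3 innate lymphoid cells 1 rose at 4 h in WT and in CIS KO, of 3 stromal genes 1 rose in WT at both times and in CIS KO at 4 h, and no erythroid or platelet gene passed the count filter. The type I interferon list passed camera in no response, with 2 of 13 genes higher and 1 lower in WT at 4 h, also over the list alone, among them Rsad2 (2.42 ± 0.34).

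**Figure D2:**
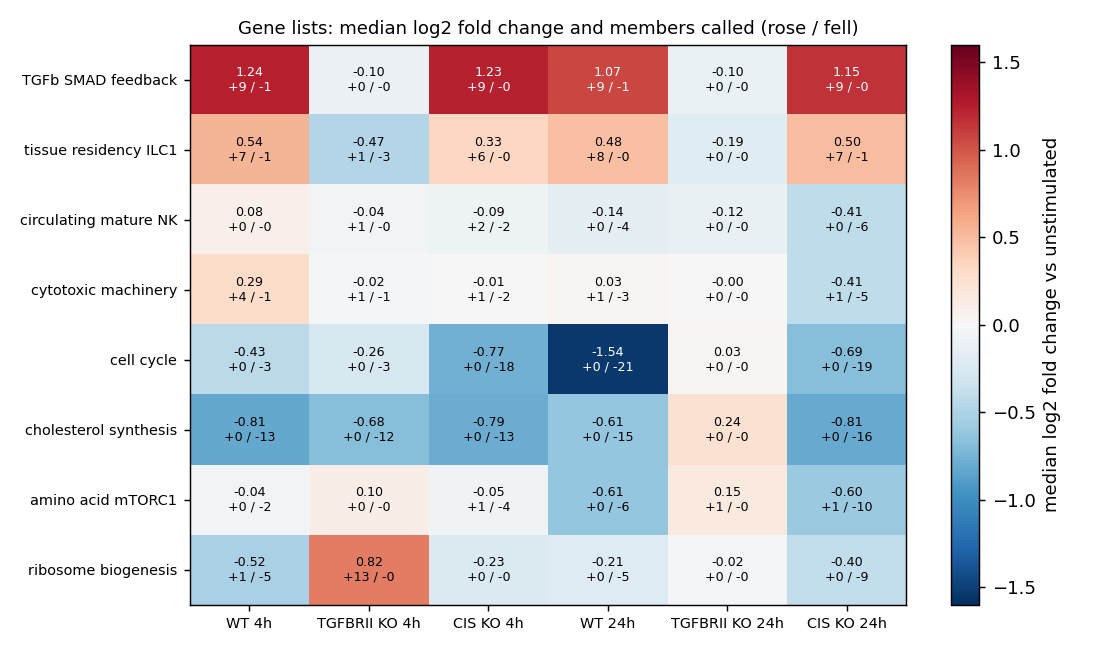
Median log2 fold change against unstimulated cells for 8 gene lists (vertical) in the 6 responses (horizontal), as colour and as the upper number, with the numbers of members that rose and fell below it. The feedback list had a median of 1.07 in WT at 24 h and 1.15 in CIS KO, and the cell cycle list had -1.54 in WT and -0.69 in CIS KO.

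The response of TGFBRII KO differed from that of WT by test in 778 genes at 4 h (407 higher, 371 lower) and 1105 at 24 h (708 higher, 397 lower). At 24 h the feedback list was lower in the knockout's response (7 of 14 lower; 7 lower and 1 higher adjusted over the list alone), with Ski at -1.94 and Tgfb3 at -3.40, as was residency (7 of 14; 7 and 1), with Itgae at -5.47 ± 0.93 and Nt5e at -3.56. Cell cycle genes were higher, 20 of 21 (21 adjusted over the list alone), with Ccna2 at 2.43 ± 0.21. The same direction held for cholesterol genes (14 of 17; 15 adjusted over the list alone; Nsdhl 1.54) and amino acid genes (6 of 14; 8 adjusted over the list alone; Mthfd2 1.53 ± 0.15). At 4 h ribosome biogenesis was higher in the knockout's response, 12 of 16 in either adjustment, with Nolc1 at 2.14 ± 0.23, and feedback (8 of 14; 8 lower and 1 higher adjusted over the list alone) and residency (6 of 14; 8) were lower. These 3 lists at 4 h and the 5 at 24 h held with an estimated correlation. The cholesterol list at 4 h had 0 of 17 genes called in either adjustment (median 0.199, adjusted p = 0.825 with an estimated correlation). The 4 h count was 491 by DESeq2 (224 higher, 267 lower) and 514 without WT 4 h replicate 1, 485 with a replicate block, and without WT 4 h replicate 4 there were 240 higher and 389 lower, with 363 of the 778 calls shared. Library size alone gave 63.1% of the 4 h calls higher in place of 52.3%, so the balance is not settled. Over the genes called in WT at 24 h, the median change in the WT direction was 0.713 ± 0.0128 in WT (n = 4), the group they were chosen in, -0.0143 ± 0.0339 in TGFBRII KO (n = 3) and 0.526 ± 0.0473 in CIS KO (n = 4). The values at 4 h were 0.836 ± 0.164 (n = 2), 0.0635 ± 0.0659 and 0.532 ± 0.0619, with the last at 0.287 without WT 4 h replicate 4. That fit chose another set of WT genes, so the shift does not show that the CIS KO response is unstable. Calls in WT and CIS KO, which share no library, had 582 higher genes in common at 24 h where independent lists would share 121.7, and 607 lower where they would share 138.

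Set against WT at the same time, TGFBRII KO cells carried few differences before stimulation. Itga1 was at 110.1 ± 4.60 CPM in TGFBRII KO and 202 ± 19.6 in WT (log2 -0.88 ± 0.14), Ski was lower by -0.60 ± 0.13 and the interferon-induced gene Ifi208 by -2.21 ± 0.26, while Mmp9, a matrix protease, was higher by 0.76 ± 0.13. With Y-linked Ddx3y at 3.12 ± 0.54, 7 genes were higher and 8 lower, and 929 had an unadjusted p under 0.05. No list held with an estimated correlation. Leaving out WT unstimulated replicate 1 gave 79 calls and leaving out TGFBRII KO replicate 1 gave 9, and RLE factors gave 12 higher and 8 lower. The depth covariate gave 64 calls, the male share 8 and the fit without a low-count filter 173.

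Under TGFB1 the difference between TGFBRII KO and WT was wide. Vipr2, a neuropeptide receptor gene, was at 2.12 ± 0.85 CPM in TGFBRII KO and 139.7 ± 0.887 CPM in WT (n = 2) at 4 h. At 24 h Rnase6, an antimicrobial ribonuclease, was at 0 in the knockout, at least 31.6-fold lower. Ccna2 was higher by 2.42 ± 0.16, Prf1 by 1.53 ± 0.17, Havcr2 by 1.85 ± 0.16 and Ccl9 by 4.22 ± 0.29. All 21 cell cycle genes, 16 of 17 cholesterol genes and 8 of 14 amino acid genes were higher (21, 16 and 9 adjusted over the list alone), and 9 of 14 feedback genes were lower and 1 higher (10 and 1). In all, 1181 genes were higher and 1037 lower. Glycolysis and hypoxia (6 of 14 and 6 of 12 higher; 9 and 8 adjusted over the list alone) had adjusted p = 0.582 and 0.528 with an estimated correlation. At 4 h, 578 were higher and 634 lower, with Nop58, a nucleolar protein of ribosome assembly, at 1.35 ± 0.13 and 12 of 16 ribosome biogenesis genes higher (also over the list alone), and with Ski at -2.91 ± 0.14. The fit on these 5 libraries called 741 genes at 4 h, the male share as a covariate gave 664, and without WT 4 h replicate 1 there were 366 higher and 444 lower. Library size alone gave 701 higher and 530 lower, and without WT 4 h replicate 4 there were 312 and 620, with 568 of the 1212 calls shared, so the balance is not settled.

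Unstimulated CIS KO and WT cells differed in 328 higher and 304 lower genes. Smad3, which carries TGF-β signals to the nucleus, was lower in CIS KO (27.9 ± 9.97 against 66.0 ± 12.6 CPM; log2 -1.25 ± 0.27), as was Ski (-0.56 ± 0.13), in a feedback list with 2 of 14 genes lower (4 adjusted over the list alone; adjusted p = 0.0811 with an estimated correlation). The cytokine gene Osm (1.17 ± 0.33), Cdkn1a (0.66 ± 0.11) and Ly6c2 (0.71 ± 0.14) were higher, as were Prf1 (0.51 ± 0.15) and Gzmb (0.69 ± 0.18), the latter with counts that level off. Metabolic lists lay higher but did not hold: glycolysis had 4 of 14 higher (8 adjusted over the list alone), oxidative phosphorylation 4 of 24 (16 higher and 1 lower) and mitochondrially encoded RNA 5 of 10 (7), with adjusted p = 0.199, 0.27 and 0.0811 with an estimated correlation. Beside these groups, Y-linked Ddx3y was higher by 3.96, Xist was at least 83.9-fold lower, and the T cell gene Bcl11b (-0.73 ± 0.19) and the myeloid gene Xcr1 (-0.67 ± 0.19) were lower. Of 3 stromal or epithelial genes 1 was higher (2 adjusted over the list alone; adjusted p = 0.16 with an estimated correlation). Among 864 genes with at least 0.05 counts per base, 133 were higher and 3 lower. With depth as a covariate 73 genes were called, with the male share 3, and with DESeq2 283. Leaving out 1 library gave from 57 (without WT replicate 3) to 1120 (without CIS KO replicate 4) calls, with 115, 241 and 74 without CIS KO replicates 1, 2 and 3 and 381 without WT replicate 2. Library size alone gave 34.9% of calls higher in place of 51.9%.

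At 24 h of TGFB1, proliferation genes were higher in CIS KO than in WT. Ccna2 was at 111 ± 10.9 CPM in CIS KO and 42.5 ± 12.3 in WT (log2 1.38 ± 0.17), Mcm3 at 1.09 ± 0.12 and Pbk, a mitotic kinase, at 2.18 ± 0.26. Of 21 cell cycle genes 17 were higher, and 21 adjusted over the list alone (adjusted p = 8.69e-05 with an estimated correlation). Itgae (-0.84 ± 0.21) and Itgam, the integrin CD11b (-1.09 ± 0.16), were lower and Havcr2 was higher (0.98 ± 0.16). The amino acid list (1 of 14 higher, 7 adjusted over the list alone) had an adjusted p = 0.0809 with an estimated correlation. The test called 228 genes higher and 108 lower, the fit on these 8 libraries 69, the depth covariate 603 and the male-share covariate 5, and without CIS KO 24 h replicate 2 there were 183 lower genes.

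At 4 h CIS KO and WT differed in 14 higher and 14 lower genes, with 895 at an unadjusted p under 0.05 and 16 called by DESeq2. Acpp, an acid phosphatase, was at 381 ± 22.5 CPM in CIS KO and 92.1 ± 2.66 in WT (log2 2.05 ± 0.22), and Nop58 was higher by 0.82 ± 0.13, in a ribosome biogenesis list with 1 of 16 higher (4 adjusted over the list alone; adjusted p = 0.00351 with an estimated correlation). Cell cycle genes had a median difference of -0.49, with 0 of 21 called (4 lower adjusted over the list alone) and an adjusted p = 0.098 with an estimated correlation. Without WT replicate 4, 5 genes were called, with the male share as a covariate 2, and with depth 73.

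The response of CIS KO to 24 h of TGFB1 differed from that of WT in 124 higher and 13 lower genes. Among 864 genes with at least 0.05 counts per base the median difference was -0.248, against 0.209 for 4586 genes below 0.01. The excess of higher genes lies in the direction that this tilt gives to sparse genes. With depth as a covariate 56 genes were higher and 1 lower. Ccna2 differed by 1.62 ± 0.21, Mcm3 by 1.05 ± 0.16, Bub1, a spindle checkpoint kinase, by 2.32 ± 0.37 and Pbk by 2.52 ± 0.32. Of the cell cycle genes, 11 of 21 differed upward (17 adjusted over the list alone), with a median difference of 0.86 and an adjusted p = 0.000601 with an estimated correlation, which was the 1 list that held. Itgam (-0.88 ± 0.23) and Ms4a6b (-0.84 ± 0.20) differed downward. The number of calls was 76 without CIS KO 24 h replicate 2, 83 in the fit on these 16 libraries and 57 with depth as a covariate. It was 212 without CIS KO unstimulated replicate 4 (172 higher, 40 lower) and 335 without a low-count filter (205 higher, 130 lower). Without WT 24 h replicate 2 there were 147 higher and 49 lower, so the number of lower genes is not settled. At 4 h the edgeR test called 0 genes, with 874 at an unadjusted p under 0.05, and DESeq2 called 0. The fit without a low-count filter called 68 genes there, and the fit without WT 4 h replicate 1 called 1. The cell cycle list at 4 h had a median difference of -0.40, with 0 of 21 genes called in either adjustment and an adjusted p = 0.472 with an estimated correlation. Mitochondrially encoded RNA had 6 of 10 genes lower adjusted over the list alone at that time, with an adjusted p = 0.117 with an estimated correlation.

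**Figure D3:**
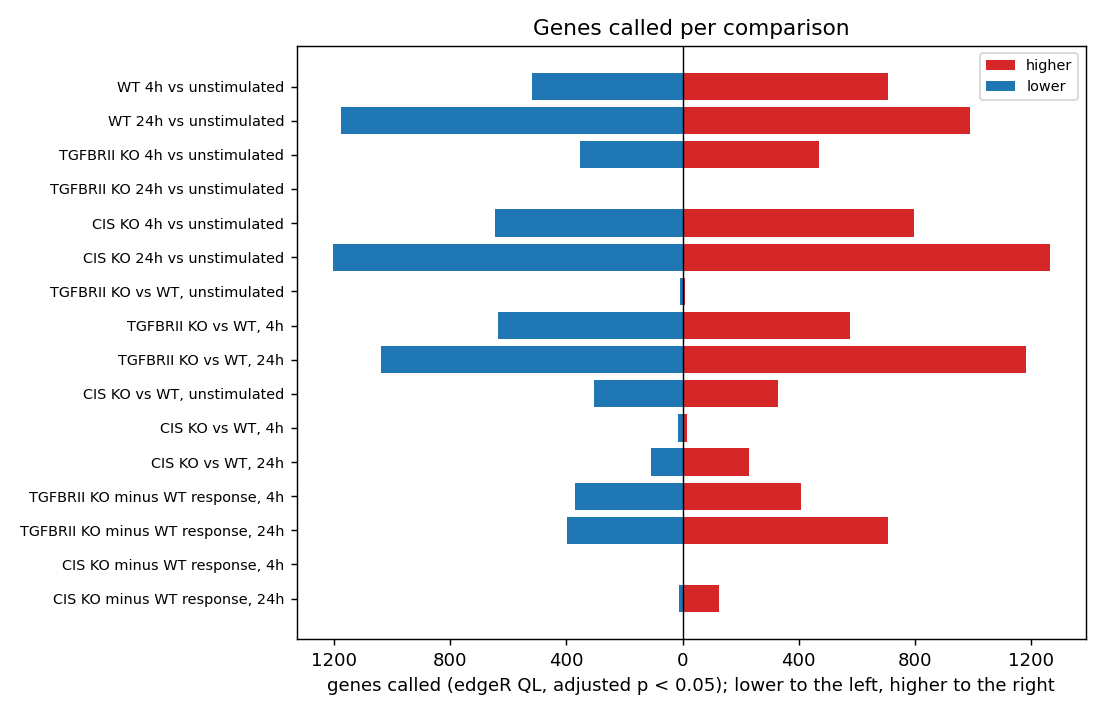
Number of genes called by edgeR's quasi-likelihood test in each of the 16 comparisons, with higher genes to the right and lower genes to the left. WT at 24 h had 989 higher and 1177 lower genes, TGFBRII KO at 24 h had 2 and 0, and CIS KO at 24 h had 1264 and 1205.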

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

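The tests of TGF-β signalling left in TGFBRII KO, of the totals of its libraries, of levelling off in abundant genes, of the smaller cell cycle fall in CIS KO and of the depth and male-share covariates were chosen only after the results were seen, though the predictions for the covariates in unstimulated cells and at 4 h in TGFBRII KO were written before their outcomes.

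Unstimulated CIS KO and WT cells differed in 632 genes by the test. Chance is argued against: the real split of the 8 libraries called 1109 genes in a fit of their own, and the highest other called 2. As many were called in 1 of 35 splits, the smallest share that 35 splits can give. The calls were not confined to abundant genes, since 347 of the 458 calls below 0.05 counts per base stayed when only such genes were fitted. This fit cannot decide on levelling off, because the median slope on depth still ran from 1.43 to 1.01 over the bins below 0.05. A wider trend with the lower depth of the CIS KO libraries could account for part: with depth as a covariate 63 of the 632 calls stayed, while their median size went from 0.614 to 0.388 and their median standard error from 0.165 to 0.142. The correction for levelling off kept 561 of 594 calls but decides nothing, because the median change of the 864 abundant genes was 0.28 before it and 0.286 with it. With the male share as a covariate 3 calls stayed, as the prediction for sex had it, but through an error of 0.312 at a size of 0.645. The male share followed genotype (correlation 0.979 over 22 libraries), so sex and knockout cannot be told apart. Neither can other cells: 2 of 12 T, B, myeloid and innate lymphoid marker genes were called, Bcl11b and Xcr1, both lower. Of 3 stromal or epithelial genes, 1 was higher.

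In TGFBRII KO cells 824 genes changed at 4 h, with the ribosome biogenesis list higher and the cholesterol list lower. TGF-β signalling left in the knockout is argued against by the feedback genes called in WT: over these 10 genes the median change in the WT direction was -0.095 in TGFBRII KO and 1.466 in WT. Lower depth at 4 h is argued against by the totals, 796503 ± 84590 at 4 h and 802346 ± 21476 in unstimulated cells, a difference of -5843, and with totals so alike the depth covariate, under which 824 of the 824 calls stayed, had nothing to remove. The 10 splits of the 6 libraries are too few for a share under 0.05, with 1336 genes in the real split, in 1 of the 10, and 0 as the highest other. Handling or medium at 4 h, which no group without TGFB1 shows here, stays open as an untested explanation.

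Cell cycle genes fell less at 24 h in CIS KO than in WT, with a median difference in response of 0.86 over 21 genes, while at 4 h the difference was -0.40 (adjusted p = 0.472 with an estimated correlation), with 18 genes lower in CIS KO and 3 in WT. Depth and a lone library are argued against: the median difference was 0.815 with depth as a covariate, and without 1 of the 16 libraries it ran from 0.755 to 1.023. With the male share as a covariate it was 0.87, but that covariate cannot remove a response that depends on sex, which cannot be told apart from genotype here because the male share follows it. The response differed in 137 genes by the test, and 4 of 100 splits, the real one included, called as many as the real 83. That share is under 0.05 but not adjusted for the other comparisons split, and the highest other called 778. That split swapped CIS KO 24 h replicates 1 and 4 with WT 24 h replicates 1 and 2, and the unstimulated replicate 4 of CIS KO with that of WT. These splits exchanged genotype labels within each condition, so a genotype difference at a single time can itself make or hide a response difference. The share therefore cannot decide on the response difference. Chance is not excluded, and a structure of the samples, not traced to a library, stays open. A smaller TGFB1 effect on proliferation at 24 h without CIS is a hypothesis that these data leave open, and the 4 h median lies on the other side.

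By the test of the difference itself, the response of TGFBRII KO differed from that of WT in 778 genes at 4 h and 1105 at 24 h, and the response of CIS KO in 137 at 24 h. For the TGFBRII KO response difference at 24 h, 2 of 100 splits, the real one included, called as many as the real 1193. The highest other, which kept the 24 h libraries in place and exchanged unstimulated libraries of the genotypes, called 1385. Labels were exchanged within each condition here too, so these splits cannot decide on the response difference. Chance is argued against for WT at 24 h (1644 in the real split, highest other 6), CIS KO at 24 h (1421, highest other 0), CIS KO at 4 h (1485, highest other 0), TGFBRII KO against WT at 24 h (2078, highest other 2) and CIS KO against WT at 24 h (69, highest other 0). Each had 1 of 35 splits as large, the smallest share that 35 splits can give, without adjustment for the number of comparisons. For TGFBRII KO at 24 h, the 10 splits are too few for a share under 0.05, with 206 in the real split, in 1 of 10, and 0 as the highest other.

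Chance cannot be excluded for TGFBRII KO against WT in unstimulated cells, where 2 of 35 splits called as many as the real 20. The highest other called 481, with WT replicate 1 placed among the TGFBRII KO libraries, which points to a structure of the samples. The T, B, myeloid and innate lymphoid lists had 0 of 12 genes called between these groups by edgeR's test.

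In 6 of 39 groups and measures 1 library lay far from its group, where chance alone gives about 1 in 20, but 3 of the 6 rest on a few reads and the tally is not held against that rate. Only groups of 4 libraries were tested, so neither the TGFBRII KO groups nor WT at 4 h were checked. The total count of CIS KO 24 h replicate 2 was 1403005, with the others from 590009 to 710013. CIS KO 4 h replicate 1 had 12872 genes detected, with the others from 11961 to 12097. Itgae was at 7.42 CPM in CIS KO unstimulated replicate 2 and from 1.96 to 2.77 CPM in the others, which is 4 reads against 1 to 2. Xist was at 5.22 CPM in CIS KO 24 h replicate 4 and at 2.38 CPM in CIS KO 4 h replicate 2, with 0 in the others of each group, which is 3 reads and 1 read, and in a group otherwise at 0 any read stands out. The Y-linked sum was 124 CPM in WT 24 h replicate 2 and from 1.48 to 14.8 CPM in the others.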

How the results depend on the processing

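The depth, male-share, levelling-off and counts-per-base alternatives were chosen only after the results were seen. Over all alternatives, 6417 list values kept their call or lack of one, 154 gained a call, 200 lost one and 11 reversed. For named genes these numbers were 27357, 468, 1638 and 4. A value called in neither fit counts as kept whatever its sign, so direction was compared only where either fit called it. The cause was not tested except where stated. Carry-over, the median change in the WT direction, is taken over the genes that each alternative calls in WT. It therefore also moves with that gene set, and the WT value on the same set is not given.

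DESeq2 called 434 genes for TGFBRII KO at 4 h, 0 at 24 h, 283 for CIS KO against WT unstimulated, 16 at 4 h, 223 at 24 h and 491 for the TGFBRII KO response difference at 4 h, and its carry-over of the WT 24 h calls in CIS KO was 0.618. Library size alone gave 0 for TGFBRII KO at 24 h, and moved the median of all genes to -0.112 for WT at 4 h, -0.114 for CIS KO against WT unstimulated and 0.117 for the CIS KO response difference at 24 h. RLE factors moved no number of calls by over 1.5 times, but 12 in place of 7 genes were higher in TGFBRII KO against WT unstimulated. With no low-count filter, more genes with few counts entered, and the counts were 79 for TGFBRII KO at 24 h, 173 for TGFBRII KO against WT unstimulated, 1197 for CIS KO against WT unstimulated, 81 at 4 h, 68 and 335 for the CIS KO response differences at 4 h and 24 h, and a 4 h carry-over in CIS KO of 0.454. Fits on only the compared groups called 722 for WT at 4 h, 1336 and 206 for TGFBRII KO at 4 h and 24 h, 1421 for CIS KO at 24 h, 741 for TGFBRII KO against WT at 4 h, 1109, 12 and 69 for CIS KO against WT unstimulated, at 4 h and at 24 h, and 83 for the CIS KO response difference at 24 h, with a 4 h carry-over in CIS KO of 0.687.

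Replicate numbers were not taken to pair the samples, because not every same-numbered pair correlated over 0.1: it did in 1 of 8 pairs in WT, 4 of 9 in TGFBRII KO, 2 of 12 in CIS KO and 2 of 26 between genotypes, and 0 of 10, 7 of 9 and 5 of 12 libraries correlated best with their own number. In TGFBRII KO all 9 pairs were positive (0.015 to 0.198), and the Y-linked sum was highest in replicate 2 at each time. These values are a hint of shared origin from the data and not from the design. The main p-values of that genotype treat its libraries as independent. The WT sums recurred in replicate 1 (19.1, 22.5 and 14.8 CPM at the 3 times), replicate 2 (91.1 and 124, with no 4 h library) and replicate 3 (7.54 and 5.96, with none), a hint of the same kind, but not in replicate 4 (1.38, 20.04 and 1.48). With a replicate block the counts were 662 for WT at 4 h, 0 for TGFBRII KO at 24 h and 485 for the TGFBRII KO response difference at 4 h, with a 4 h carry-over in CIS KO of 0.730.

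With depth as a covariate, TGFBRII KO had 1360 calls at 4 h and 13 at 24 h, TGFBRII KO against WT unstimulated 64, CIS KO against WT 73 unstimulated, 73 at 4 h and 603 at 24 h, and the CIS KO response difference at 24 h 57. With the male share, TGFBRII KO against WT had 8 unstimulated and 664 at 4 h, and CIS KO against WT 3, 2 and 5 at the 3 times. Genes below 0.05 counts per base gave 24 and 392 for TGFBRII KO and CIS KO against WT unstimulated, with fewer genes tested, and a 4 h carry-over in CIS KO of 0.595.

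For lists, camera's direction decides a reversal and the median is printed, which kept its sign for glycolysis at 4 h with depth and, below 0.05 counts per base, in each case but NK receptors at 24 h. Reversed with depth as a covariate were Gzmc in WT at 4 h (-0.004), oxidative phosphorylation in WT at 4 h (-0.018), glycolysis in the CIS KO response difference at 4 h (-0.022), and cytotoxic machinery, glycolysis and oxidative phosphorylation in that at 24 h (0.039, 0.113 and 0.075). With the male share they were Myl10 (0.002) and Havcr2 (-0.249) in unstimulated cells, oxidative phosphorylation at 4 h (0.306), and Klra1 (0.119) and cytokines (0.024) at 24 h, all between CIS KO and WT. With genes below 0.05 counts per base they were oxidative phosphorylation in WT at 4 h (0.002), NK receptors in the CIS KO response differences at 4 h (-0.015) and 24 h (0.283), and oxidative phosphorylation in the latter (-0.022).

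Leaving out each library in turn gave these ranges of calls: WT 583 to 1264 at 4 h and 1811 to 2024 at 24 h, TGFBRII KO 403 to 586 and 0 to 3, CIS KO 1076 to 1285 and 1632 to 2814. Against WT, TGFBRII KO ran from 9 to 79, 810 to 1126 and 1641 to 2090 at the 3 times, and CIS KO from 57 to 1120, 5 to 32 and 240 to 400. Response differences ran from 514 to 789 and 829 to 1254 for TGFBRII KO, and from 0 to 1 and 76 to 212 for CIS KO. Carry-over ran from 0.0231 to 0.0958 in TGFBRII KO and 0.287 (without WT 4 h replicate 4) to 0.787 (without WT 4 h replicate 1) in CIS KO at 4 h, and from -0.0394 to 0.00406 and 0.493 to 0.582 at 24 h, where the TGFBRII KO value turned positive without its 24 h replicate 2. Depths of 297561 to 1403005 counts limit what can be detected in genes with few counts.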

Other observations

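The tests of DNA near Cish were chosen only after the result was seen, and the genes named here fell outside the naming rule where the report does not name them.

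Some genes differed between CIS KO and WT at all 3 times. Rpl29, a ribosomal protein gene, was lower by -4.23 ± 0.41 in unstimulated cells and -4.52 at 4 h. Acpp was higher by 0.91 ± 0.18 in unstimulated cells, 2.05 at 4 h and 1.69 at 24 h, Gpd1l, a glycerol phosphate dehydrogenase relative, by 0.58, 0.98 and 0.97, and Mapkapk3, a stress kinase, was lower by -0.50, -0.88 and -0.73. Btbd11, Stk10, Acvrl1, Rasgrp2 and Adgre5 lay elsewhere in the genome. Of these 9 autosomal genes 4 lay within 20 Mb of Cish on chromosome 9, against 212 of the 9750 genes tested with a position (one-sided Fisher's exact p = 2.51e-05). Without Rpl29, which prompted the question, 3 of 8 did (exact p = 0.000524). DNA around Cish that came with the targeted allele is a candidate explanation for these neighbours, and an effect of the missing Cish on them was not tested.

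The hypothesis that time in culture alone gave the WT response at 24 h was tested on TGFBRII KO. The median change of the genes called in WT, taken in the WT direction, was -0.02 of the WT value there, which argues against time in culture as the whole cause, as far as TGFBRII KO cells were kept in the same way.

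The Y-linked sum was highest in replicate 2 of WT and of TGFBRII KO wherever a group held that replicate. In WT replicate 2 it was 91.1 CPM in unstimulated cells and 124 CPM at 24 h, and in TGFBRII KO replicate 2 it was 388, 451 and 376 CPM in unstimulated cells, at 4 h and at 24 h.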
